A study of Rattus norvegicus with 47 samples.

How the data were processed

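RNA sequencing of prefrontal cortex taken from rats on postnatal day 1 was analysed in 47 libraries. Per the labels' protocols, RNA was purified with an RNeasy kit, poly(A) RNA was selected, and strand-specific libraries were made with the NEBNext Ultra Directional kit. The values used were read counts per Ensembl gene ID, deposited by the authors as whole numbers in 1 table for all samples, with no normalization. Per the submitters' processing notes, FastQC, featureCounts and DESeq2 were used, with no version or role recorded. The aligner, the genome build and the strand setting of the counting are not given in the sources used here, so reads of overlapping or near-identical genes were taken as counted. The table held 32883 gene IDs. Its 15 further entries named no gene and held no value, so they took no share of the counts. Each column was assigned to the sample whose title holds the same number.

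Samples were placed in 8 groups by the treatment and sex in the labels: control, BFR, OPFR and FM550, each female and male. Every group held 6 libraries except OPFR females, with 5. Replicate numbers follow the order of the records and pair no samples. The labels do not say which samples came from separate litters or animals, so p-values measure the spread between these samples only. No library was a copy of another: the smallest chi-square per gene between 2 libraries was 8.74, where repeated draws of 1 library give about 1.

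The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 8 groups (a minimum count of 10 and a minimum total of 15), which left 17135 of the 27198 IDs that had at least 1 read. Library sizes were scaled by TMM, with factors from 0.95 to 1.10. One quasi-likelihood model was fitted to all 47 libraries with a mean for each group, and each comparison was a contrast in it. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, with no fold minimum. All tests were two-sided. CPM values were computed from the TMM-scaled library sizes, and standard errors of log2 fold changes come from the quasi-likelihood F statistic. Components were computed on the 2000 genes with the most variable log2 CPM, with a prior count of 2.

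The files do not pair the gene IDs with names. The reference gene table used here (assembly GRCr8, 47357 genes) holds no Ensembl IDs, and 0 of the 32883 IDs matched it. The gene lists chosen beforehand for neuronal, glial, vascular, hormonal and xenobiotic functions were therefore not tested, and no check of GC content or gene length was made. The rule for named genes, which asked for symbols, was limited to at most 2 IDs each way per comparison: among called genes with an average log2 CPM of at least 1, those with the highest and lowest log2 fold change. ENSRNOG00000047261 is named by that rule for 3 comparisons, and its values in the others were looked at after that.

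Total counts ranged from 41.1 to 73.4 M per library, and between 19618 and 21413 IDs had a read in each. The common biological coefficient of variation was 0.19. The procedure was tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 of the 17135 genes changed. With 6 BFR against 6 control males it recovered 49.3% of 67 genes changed 1.25-fold, 88.1% of 67 changed 1.5-fold and 93.9% of 66 changed 2-fold, with 8 false calls. With 5 OPFR against 6 control females the shares were 38.8%, 80.6% and 93.9%, with 9 false calls. The changed genes were drawn from those with a mean log2 CPM of at least 1. The dispersions were estimated with a term for the 7 libraries whose titles are numbered 1 to 7. These figures describe the simulated counts only. They do not measure recovery or false calls in the real pooled fit, where part of the control group stood apart.

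Alternatives fixed before the data were examined were DESeq2 1.42.0 (Wald test), RLE size factors, no filter on low counts, a fit of only the groups compared, 2 surrogate variables from sva 3.50.0, limma 3.58.1 voom with sample weights, and leaving out each library in turn. Alternatives added after the data were seen were a term for the 7 libraries whose titles are numbered 1 to 7, leaving those libraries out, leaving out OPFR females 4 and 5, leaving out both sets, leaving out OPFR libraries 31 to 35, and a term for log2 library size. Comparisons that share control libraries were set beside 20 simulations of unchanged groups and beside fits with the controls of each sex split 3 and 3, averaged over 10 draws.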

Results

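Prefrontal cortex of newborn rats was profiled after daily exposure of their mothers during gestation. The question posed by the study's title is whether the effects of the commercial FireMaster flame retardant mixture FM550 differ by sex and whether they come mostly from its organophosphate esters. BFR stands for the 2 brominated esters of the mixture (EH-TBB and BEH-TEBP) at 1000 µg per day, OPFR for triphenyl phosphate with its isopropylated form at 1000 µg per day, and FM550 for the whole mixture at 2000 µg per day, so the doses of the groups differ. There were 47 libraries: 6 females and 6 males in each of the control, BFR and FM550 groups, and 5 females and 6 males in the OPFR group. Libraries held 58.5 ± 7.4 M counted reads (SD, n = 47). Group means lay between 52.1 ± 5.2 M in control females (SD, n = 6) and 63.1 ± 7.8 M in FM550 males (SD, n = 6). Genes are given by Ensembl ID because the files do not pair the IDs with names.

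Female and male libraries were separated by a small set of genes. In controls, 14 genes differed between the sexes, 7 higher in females and 7 higher in males (edgeR quasi-likelihood, adjusted p below 0.05). ENSRNOG00000051257 measured 55.8 ± 11.8 CPM in control females and 0.304 ± 0.110 CPM in control males (SD, n = 6 each), a log2 difference of 7.50 ± 0.26 (SE) with an edgeR adjusted p of 4.99e-26. ENSRNOG00000055225 was higher in females by 7.61 ± 0.36 on the log2 scale (edgeR adjusted p = 4.52e-21). ENSRNOG00000060496 measured 39.4 ± 2.4 CPM in control males and 0.101 ± 0.032 CPM in control females (SD, n = 6 each), a log2 difference of -8.59 ± 0.16 (SE) with an edgeR adjusted p of 1.11e-37. ENSRNOG00000060617 had 148 to 316 reads in each control male and at most 1 read in any control female. Of the 14 genes, 10 differed over 8-fold, 3 higher in females and 7 higher in males. For all 10, the 23 female and 24 male libraries did not overlap in CPM, so every library lay on the side of its label. Averaged over the 4 treatments, 22 genes differed between the sexes, 11 each way, and all 14 control genes were among them in the same direction. The control count of 14 was 13 with a term for libraries 1 to 7, described next, and 12 without them. It rose to 436 without Control female 1, to 38 without Control female 2 and to 322 without Control male 6, and was 1923 in limma voom with sample weights.

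Part of the control group stood apart from every other library. The titles number the samples from 1 to 47, and numbers 1 to 7 are Control males 1 to 5 with Control females 1 and 2. For 390 genes, 232 lower and 158 higher, these 7 libraries did not overlap with the other 40 in log2 CPM. The next highest of the 41 runs of 7 consecutive numbers had 6 such genes, and 39 runs had 0. Among control libraries alone, with sex in the model, 2597 genes differed between numbers 1 to 7 and the other 5 controls, 1363 higher and 1234 lower in the first 7 (edgeR quasi-likelihood). A further break lay within OPFR: 2166 genes differed between numbers 25 to 30 and 31 to 35, 972 higher and 1194 lower in the first 6, which OPFR females 4 and 5 are not among. Of the 35 divisions tested within treatments, the next highest were 871 between controls 8 and 9 and 49 between FM550 libraries 39 and 40. The labels give no batch or date. Because 5 of 6 control males and 2 of 6 control females are in this run, the counts of genes against controls are given below as pooled, with a term for the 7 libraries, and without them. Without them, 1 control male and 4 control females remain.

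**Figure D1:**
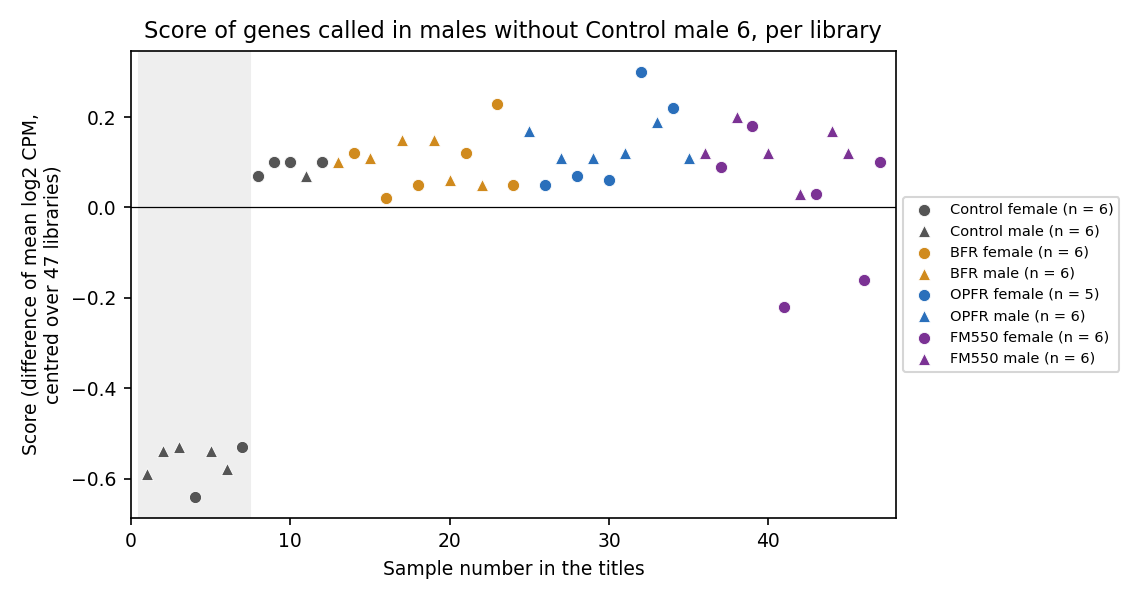
Each point is 1 of the 47 libraries, placed by the number in its title (x axis) and by the mean log2 CPM of 2425 genes called higher minus that of 1833 genes called lower in exposed males against Control males 1 to 5 (y axis, centred); colour marks treatment, circles females and triangles males, and the grey band numbers 1 to 7. The 7 libraries in the band lie between -0.64 and -0.53 and the other 40 between -0.22 and 0.30; the female controls and Control male 6 took no part in choosing the genes.

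In males, all 3 exposures differed from the pooled controls in many genes. With BFR, 793 genes were higher and 912 lower (1705 in all). ENSRNOG00000050023 was the highest, at a log2 fold change of 5.81 ± 1.73 (SE; edgeR adjusted p = 0.0267), and its level rested on BFR males 3 and 5, with 34.2 and 20.1 CPM against at most 0.395 CPM in control males. ENSRNOG00000027271 was higher by 1.23 ± 0.41 (edgeR adjusted p = 0.0486), and leaving out any of 11 of the 12 libraries took it past 0.05. ENSRNOG00000048573 had a log2 fold change of -1.71 ± 0.30 (edgeR adjusted p = 0.00123) and ENSRNOG00000001416 had a log2 fold change of -1.63 ± 0.29 (edgeR adjusted p = 0.00123). With OPFR, 1309 genes were higher and 834 lower (2143 in all). ENSRNOG00000049105 measured 8.10 ± 0.28 CPM in OPFR males and 2.66 ± 0.93 CPM in control males (SD, n = 6 each), and ENSRNOG00000043098 had a log2 fold change of 1.67 ± 0.49 (SE; edgeR adjusted p = 0.0200) that was no longer below 0.05 without OPFR libraries 31 to 35. ENSRNOG00000047351 measured 9.77 ± 1.57 CPM against 36.9 ± 12.0 CPM in controls (SD, n = 6 each), and ENSRNOG00000048573 had a log2 fold change of -1.94 ± 0.30. With FM550, 1248 genes were higher and 774 lower (2022 in all). ENSRNOG00000042869 measured 9.59 ± 2.02 CPM against 3.72 ± 1.55 CPM (SD, n = 6 each) and ENSRNOG00000049105 had a log2 fold change of 1.29 ± 0.27. ENSRNOG00000029262 and ENSRNOG00000048573 had log2 fold changes of -2.42 ± 0.71 and -1.69 ± 0.30.

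The calls in males ended when numbers 1 to 7 were modelled or left out, and most of the named genes had smaller fold changes there. With a term for numbers 1 to 7, the edgeR counts were 0 for BFR, 0 for OPFR and 0 for FM550, with 193, 531 and 345 genes at an unadjusted p under 0.05. Without the 7 libraries the counts were also 0, 0 and 0, with 194, 645 and 320 genes at an unadjusted p under 0.05, and these fits rest on 1 control male, assumed to vary like the other groups. In simulated BFR data with 1 control male, 0% of the genes given the smallest simulated change were recovered. The absence of calls without the 7 libraries therefore cannot show that small changes were absent. Recovery was not simulated for the fit with the term, where only 1 control male lies outside the 7 libraries. Its absence of calls cannot show this either. Other tools were run on the pooled libraries only and gave 2169, 2515 and 2396 genes in DESeq2 and 3933, 3559 and 3616 in limma voom. ENSRNOG00000048573 had log2 fold changes of -0.12 ± 0.22, -0.34 ± 0.22 and -0.10 ± 0.22 (SE) for BFR, OPFR and FM550 with the term, and ENSRNOG00000047351 had -1.06 ± 0.33 for OPFR. Other named genes kept fold changes near or above the pooled ones in at least 1 of these fits. ENSRNOG00000027271 had 1.82 ± 0.59 with the term and 1.93 ± 0.89 without the 7 libraries for BFR, ENSRNOG00000050023 had 3.44 ± 2.81 and 7.03 ± 4.69 for BFR, and ENSRNOG00000043098 had 1.15 ± 0.75 and 1.82 ± 1.05 for OPFR. Across the 3 exposures, which share the control males, 854 genes were called in all 3, every one in the same direction (518 higher, 336 lower). Their median log2 fold change, signed by direction, was 0.32, 0.33 and 0.34 for BFR, OPFR and FM550 pooled, 0.011, 0.028 and 0.032 with the term, and 0.033, 0.058 and 0.052 without the 7 libraries. The BFR count was 941, 1124, 1066 and 1088 without Control male 1, 2, 3 or 5, 1102 without BFR male 4 and 3042 without Control male 6. The OPFR count was 609 without OPFR libraries 31 to 35 (3 males left) and 1420, 1414 and 1428 without Control male 1, 3 or 4, and the FM550 count 1301, 1303 and 3084 without Control male 1, 5 or 6.

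**Figure D2:**
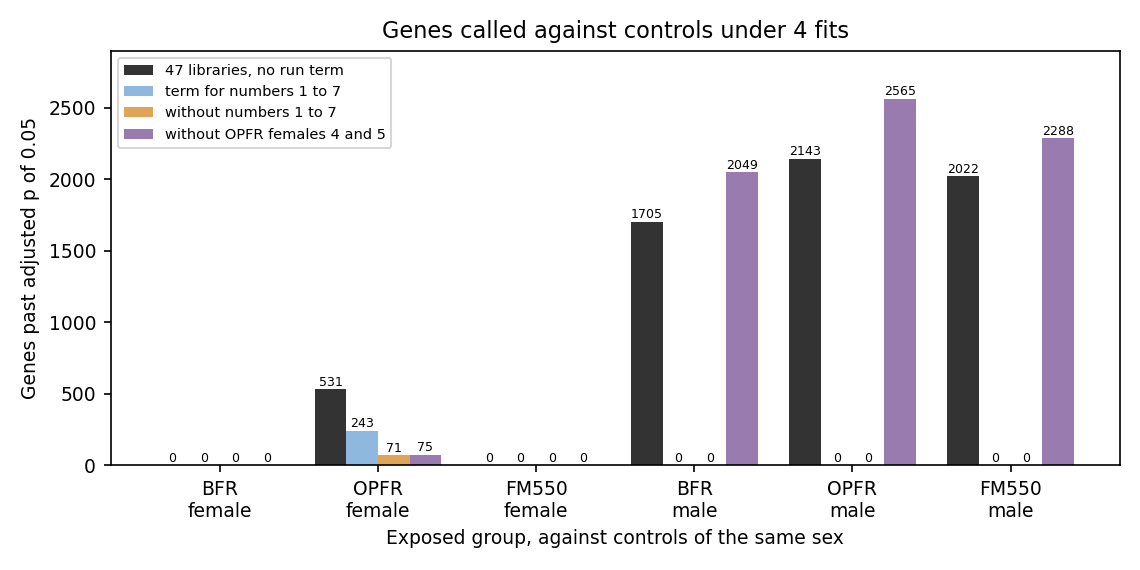
Bars give the number of genes past an adjusted p of 0.05 (y axis) for each exposed group against controls of its sex (x axis) in 4 edgeR fits: all 47 libraries, with a term for numbers 1 to 7, without those 7 libraries, and without OPFR females 4 and 5. In males, 1705, 2143 and 2022 genes pass in the first fit and 0 pass in the next 2; in females only OPFR has a count above 0, from 531 down to 71.

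In females, OPFR was the only one of the 3 exposures with genes called in the pooled edgeR fit. With OPFR, 438 genes were higher and 93 lower (531 in all). Of these, 294 were also called in OPFR males in the same direction, and 162 differed between libraries 1 to 7 and the other controls with the opposite sign. Both lists rest on controls that include that run, and OPFR males had 0 called genes with the term for it. ENSRNOG00000047261 measured 3.61 ± 0.60 CPM in OPFR females (SD, n = 5) and 11.5 ± 6.1 CPM in control females (SD, n = 6), a log2 fold change of -1.67 ± 0.27 (SE) with an edgeR adjusted p of 2.80e-04. It remained below 0.05 with the term for numbers 1 to 7 (-1.11 ± 0.21, edgeR adjusted p = 0.00341) and without those libraries (-1.10 ± 0.22, edgeR adjusted p = 0.0194), and was not when OPFR females 4 and 5 were left out as well (-0.96 ± 0.26, edgeR adjusted p = 0.259). ENSRNOG00000048573 had a log2 fold change of -1.34 ± 0.31 pooled (edgeR adjusted p = 0.0102) and of -0.40 ± 0.19 with the term (edgeR adjusted p = 0.286). ENSRNOG00000020817 had the highest log2 fold change, 5.22 ± 1.08, followed by ENSRNOG00000005707 at 2.53 ± 0.61 (edgeR adjusted p = 0.00359 and 0.0131). Both rested on OPFR females 4 and 5, where ENSRNOG00000020817 measured 28.6 and 83.7 CPM and ENSRNOG00000005707 reached 185 CPM. Without these 2 libraries their log2 fold changes were -0.11 and -1.01.

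OPFR females 4 and 5 were the outermost libraries on component 1, which held 25.2% of the variance. They had 205 and 139 genes over 8-fold above the median of the other libraries, 112 of them in common, against 74 in the next library and a median of 10. The OPFR female count of 531 was 75 without these 2 libraries, 243 with the term for numbers 1 to 7, 71 without numbers 1 to 7, 50 without OPFR libraries 31 to 35 and 0 without numbers 1 to 7 and OPFR females 4 and 5, with 3 OPFR and 4 control females left. At that size 65.7% of 67 genes changed 1.5-fold were recovered in simulated data. Leaving out 1 library gave 268 and 272 genes without Control female 1 or 2, 949, 897 and 1041 without OPFR female 1, 2 or 3, and 172 and 233 without OPFR female 4 or 5. DESeq2 gave 808 genes, limma voom 282, and a fit of only the 2 groups 52.

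**Figure D3:**
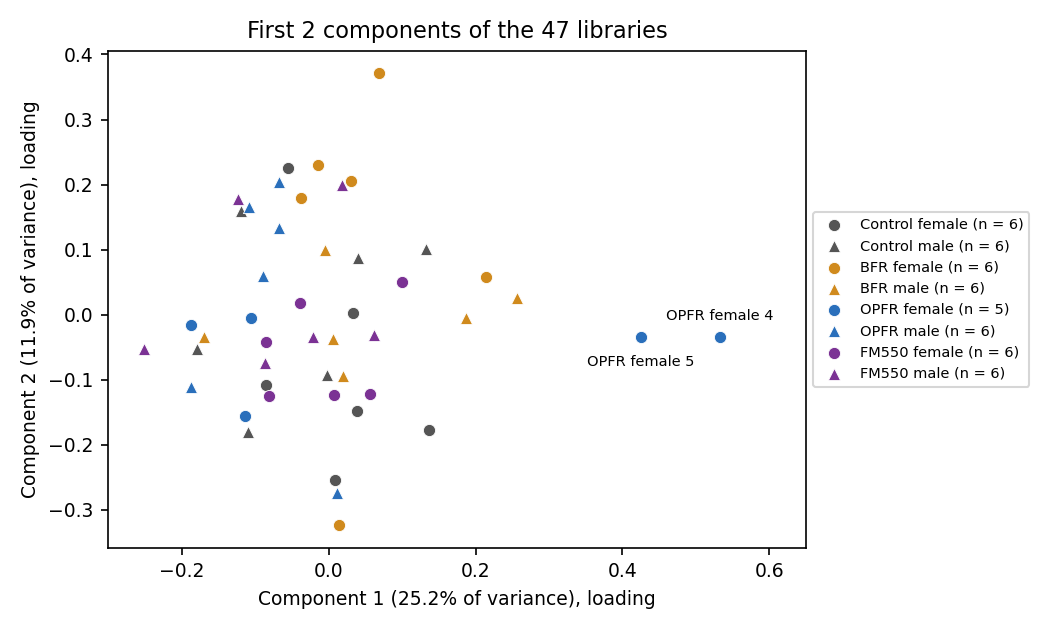
Each point is 1 of the 47 libraries on component 1 (x axis, 25.2% of the variance) and component 2 (y axis, 11.9%) of log2 CPM over the 2000 most variable genes, with colour for treatment, circles for females and triangles for males. OPFR females 4 and 5 lie farthest to the right.

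BFR and FM550 females differed from control females in 0 genes each by edgeR, with 1345 and 927 genes at an unadjusted p under 0.05. DESeq2 called 2 and 34 genes and limma voom 0 and 0. With the term for numbers 1 to 7 the edgeR counts were again 0 and 0, with 700 and 961 genes at an unadjusted p under 0.05, and without those libraries 0 and 0, with 778 and 1075. Without OPFR libraries 31 to 35 the BFR count was 2. Without FM550 female 4 or 6 the FM550 count was 9 or 8, without Control female 3 or 5 it was 1 or 2, and without BFR female 1, 2, 4, 5 or 6 the BFR count was 2. The median standard error of a log2 fold change was 0.108 in both comparisons.

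Whether an exposure acted differently in the sexes was tested as an interaction. By edgeR, 0 genes had a sex by BFR, sex by OPFR or sex by FM550 interaction, with 646, 1426 and 1560 genes at an unadjusted p under 0.05. DESeq2 called 3, 0 and 1 genes, and limma voom 0, 206 and 353. These 2 tools were run on the pooled libraries, where numbers 1 to 7 hold 5 of 6 control males and 2 of 6 control females. That run therefore enters the pooled interactions, and these counts are not read as exposure effects that differ by sex. With the term for numbers 1 to 7 the edgeR counts were 0, 0 and 0, with 180, 522 and 234 genes at an unadjusted p under 0.05, and without those libraries 0, 0 and 0, with 248, 502 and 405. Without Control male 6, 1 gene had a sex by FM550 interaction. The median standard error in the pooled fit was 0.153 for BFR, 0.157 for OPFR and 0.153 for FM550. Without numbers 1 to 7 only 1 control male remained, so the absence of calls there cannot show that interactions were absent.

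Exposed groups were compared directly with each other, where the controls enter only through the shared estimate of spread. In females, OPFR was above BFR in 194 genes and below it in 20 (214 in all). ENSRNOG00000047261 had a log2 fold change of -1.24 ± 0.26 in OPFR against BFR females (edgeR adjusted p = 0.0185) and of -1.11 ± 0.32 without OPFR libraries 31 to 35 (edgeR adjusted p = 0.218), and ENSRNOG00000018503 measured 1.17 ± 0.14 CPM in OPFR females (SD, n = 5) and 2.16 ± 0.40 CPM in BFR females (SD, n = 6). ENSRNOG00000020817 and ENSRNOG00000058560 had log2 fold changes of 4.25 ± 1.02 and 2.88 ± 0.74, which were -1.09 and -0.51 without OPFR females 4 and 5. FM550 females were above OPFR females in 6 genes and below them in 122. ENSRNOG00000031591 measured 7.55 ± 1.57 CPM in FM550 females (SD, n = 6) and 4.57 ± 0.89 CPM in OPFR females (SD, n = 5), and ENSRNOG00000017427 had a log2 fold change of 0.48 ± 0.12 (edgeR adjusted p = 0.0484). ENSRNOG00000047673 and ENSRNOG00000008700 had log2 fold changes of -8.82 ± 2.09 and -8.72 ± 2.12 and rested on OPFR females 4 and 5: ENSRNOG00000047673 measured 757 and 1645 CPM there and ENSRNOG00000008700 520 and 1290 CPM, against at most 2.47 CPM in any FM550 female for both genes. Without OPFR females 4 and 5, 0 genes differed between OPFR and BFR females and 0 between FM550 and OPFR females, and fits of only the 2 groups also gave 0 and 0, as did leaving out OPFR libraries 31 to 35. Other settings gave higher counts for OPFR against BFR, 373 in DESeq2, 1342 in limma voom and 395 with the term for numbers 1 to 7, and 203, 0 and 145 for FM550 against OPFR. With 2 surrogate variables the counts were 6 and 0. Leaving out 1 library moved both counts. OPFR against BFR called 393, 324, 342, 2 and 17 genes without OPFR female 1, 2, 3, 4 or 5, and 6, 3, 45, 104 and 544 without BFR female 1, 3, 4, 5 or 6. FM550 against OPFR called 316, 283, 274, 1 and 0 genes without OPFR female 1, 2, 3, 4 or 5, and 22, 51, 53, 27, 29 and 37 without FM550 female 1, 2, 3, 4, 5 or 6.

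Between FM550 and BFR females 0 genes differed by edgeR, with 1066 genes at an unadjusted p under 0.05, 11 by DESeq2 and 1 by limma voom. In males, FM550 and BFR differed in 1 gene, ENSRNOG00000043366, at 8.60 ± 0.31 CPM with FM550 and 6.71 ± 0.37 CPM with BFR (SD, n = 6 each), a log2 fold change of 0.36 ± 0.06 (SE; edgeR adjusted p = 0.00687) that ended past 0.05 without BFR male 6. Without OPFR libraries 31 to 35, 3 genes differed between FM550 and BFR males and 2 between FM550 and OPFR males. On all libraries FM550 and OPFR males differed in 0 genes by edgeR, with 965 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom. OPFR and BFR males also differed in 0, with 1695 at an unadjusted p under 0.05, 60 by DESeq2, 204 by limma voom and 67 in a fit of only the 2 groups. Without BFR male 2, OPFR male 1 or OPFR male 6 edgeR called 7, 3 and 2 genes. The median standard error of these male comparisons was 0.108.

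Averaged over both sexes, the pooled counts against controls were 2123 genes for BFR (892 higher, 1231 lower), 3311 for OPFR (1766 higher, 1545 lower) and 1393 for FM550 (884 higher, 509 lower). The OPFR count was 1333 without OPFR females 4 and 5 and 918 without OPFR libraries 31 to 35. With the term for numbers 1 to 7 the counts were 0, 90 (77 higher, 13 lower) and 0, with 459, 1853 and 760 genes at an unadjusted p under 0.05, and without the 7 libraries 0, 4 and 0. The OPFR count was 0 when OPFR females 4 and 5 were left out with them, with 1067 genes at an unadjusted p under 0.05. The BFR count was 1134 and 1263 without Control female 1 or 2, and the FM550 count 794, 810 and 2255 without Control female 1, Control female 2 or Control male 6.

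ENSRNOG00000047261 had its lowest group means of each sex in OPFR rats, and its call against controls depended on the libraries used. Its level was 3.61 ± 0.60 CPM in OPFR females (SD, n = 5) and 4.00 ± 0.90 CPM in OPFR males (SD, n = 6), from 2.75 to 5.65 CPM over both. Controls numbered 8 and above held 7.76 ± 1.36 CPM in females (SD, n = 4) and 6.84 CPM in the 1 male, and controls numbered 1 to 7 held 18.9 ± 3.6 CPM in females (SD, n = 2) and 16.3 ± 2.6 CPM in males (SD, n = 5). BFR groups held 8.54 ± 2.47 and 7.90 ± 0.95 CPM and FM550 groups 7.00 ± 1.60 and 5.61 ± 1.74 CPM in females and males (SD, n = 6 each). Over both sexes OPFR against control was -1.78 ± 0.18 on the log2 scale (SE; edgeR adjusted p = 9.16e-09), -0.94 ± 0.18 with the term for numbers 1 to 7 (edgeR adjusted p = 0.00893) and -0.94 ± 0.20 without those libraries (edgeR adjusted p = 0.0673). It was -0.87 ± 0.21 when OPFR females 4 and 5 were also left out (edgeR adjusted p = 0.218). In males alone it was -1.89 ± 0.25 pooled (edgeR adjusted p = 6.33e-06), -0.76 ± 0.25 with the term (edgeR adjusted p = 0.999) and -0.78 ± 0.34 without the 7 libraries (edgeR adjusted p = 0.915). FM550 against control was -1.05 ± 0.17 pooled and -0.21 ± 0.18 with the term (edgeR adjusted p = 0.999). BFR against control was -0.66 ± 0.17 pooled and 0.18 ± 0.18 with the term (edgeR adjusted p = 0.999). Between OPFR and BFR males the log2 fold change was -0.98 ± 0.25 (edgeR adjusted p = 0.123). With the term the adjusted p of edgeR was 0.0132. Without OPFR libraries 31 to 35, with 3 OPFR males left, the log2 fold change was -0.84 ± 0.32 (edgeR adjusted p = 0.782).

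**Figure D4:**
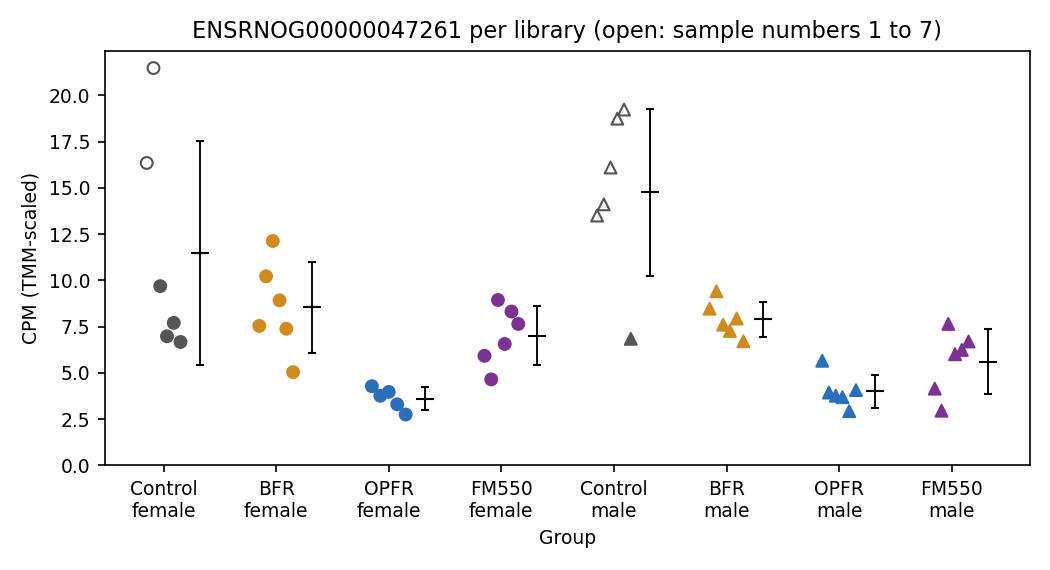
Points give the CPM of ENSRNOG00000047261 (y axis) in each library of the 8 groups (x axis), with open symbols for numbers 1 to 7 and bars for the mean and SD of each group. The 11 OPFR libraries lie between 2.75 and 5.65 CPM.

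How far the mixture followed each constituent was read from fold changes against controls of the same sex, across 17135 genes, which are not independent replicates. In males the Pearson correlation of FM550 with OPFR was 0.71 and with BFR 0.44, and the Spearman correlations were 0.69 and 0.68. Because both sides share the controls, simulated groups with no effect gave 0.50 and 0.51 (Pearson) and 0.45 and 0.46 (Spearman). The covariance of FM550 with OPFR in males was 0.0803 against 0.0343 simulated, and that of FM550 with BFR 0.0456 against 0.0346. With the controls split 3 and 3 the covariances were 0.0404 and 0.0189. Libraries numbered 1 to 7 fell in both parts of the control males in every draw. The split therefore removes shared libraries but not the run they belong to. With the term for numbers 1 to 7 they were 0.0942 and 0.059, against 0.0983 and 0.0979 simulated in the same fit. Over genes with an average log2 CPM of at least 3 the pooled covariances were 0.0349 and 0.0267, against 0.00684 and 0.00686 simulated. The Spearman correlations there were 0.81 with OPFR and 0.88 with BFR. With the term the covariances over these genes were 0.0462 and 0.0169, against 0.02 and 0.0199 simulated. By rank neither pair was above its simulated value there. Spearman's rho with the term was 0.49 with OPFR and 0.55 with BFR, against 0.72 simulated for each. In females the covariance of FM550 with OPFR was 0.0145 against 0.0347 simulated and with BFR 0.0361 against 0.0346, and with the controls split they were -0.0185 and -0.00559. The female Spearman correlations were 0.4 with OPFR and 0.49 with BFR, against 0.43 and 0.45 simulated. With the controls split they were 0.04 and 0.03. By rank the OPFR pair was near its simulated value, so its low covariance alone does not show that FM550 followed OPFR less than unchanged groups would.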

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

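The tests of libraries 1 to 7 and of OPFR females 4 and 5 were chosen after the results were seen, while the test of shared controls and the regrouping of samples were written before. In the comparison of FM550 with OPFR in males, the second set of genes was also looked at afterwards.

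In 11 cases, 3 on whole libraries and 8 on named genes, 1 library lay far from the others of its group, with a gap to its nearest neighbour that took an unusual share of the group's range. Chance gives about 1 such case in 20 groups, and the number of groups checked was not recorded, so the 11 cases have no expected number beside them. Control female 5 had the highest total count of its group, 62.0 M reads (gap 0.626 of the range). OPFR female 3 was lowest on component 2 (gap 0.807). Control male 6 was highest of the control males on the score of the genes shared by the 3 male comparisons, at 0.04 (gap 0.933). That library was also lowest of its group for ENSRNOG00000048573, at a log2 CPM of 1.29 (gap 0.85), and for ENSRNOG00000047261, at 2.78 (gap 0.657). ENSRNOG00000027271 was highest in BFR male 2 at 6.16 (gap 0.672) and, in controls, in Control male 1 at 5.41 (gap 0.759). ENSRNOG00000048573 was highest of the OPFR males in OPFR male 3 at 1.15 (gap 0.666), ENSRNOG00000001416 highest of the BFR males in BFR male 6 at 3.74 (gap 0.697), and ENSRNOG00000043098 highest of the control males in Control male 2 at 3.41 (gap 0.67). ENSRNOG00000018503 was lowest of the BFR females in BFR female 6 at 0.55 (gap 0.632).

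The first pattern is the 1705, 2143 and 2022 genes called in males. Library size as the whole cause is argued against, since 1612 BFR genes were called with log2 library size in the fit. A batch of libraries 1 to 7 is consistent with the controls held out of the gene choice: Control females 1 and 2 scored at most -0.53, and the 5 other held-out controls at least 0.07. An exposure effect in males stays open: without the 7 libraries the shared genes had a median signed log2 fold of 0.0576 in OPFR males, but only 1 control male remained. Simulated data of that size recovered 37.3% of 67 genes changed 1.5-fold and 0% of the genes given the smallest simulated change. The absence of calls there therefore cannot decide about small changes. Of 100 groupings of the males, the real one included, the real split gave the most genes for each exposure. It gave 1145 for BFR in the fit of these groups, 950 for OPFR and 1230 for FM550. The highest others were 1, 0 and 209. The real split also sets 5 of the 7 libraries on one side, so regrouping cannot tell exposure from the run.

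For the second pattern, the 531 genes called in OPFR females, libraries 1 to 7 as the whole cause are argued against, since 243 genes were called with a term for them. The 2 OPFR females that stand apart may account for most of the count, which was 75 without them. The median signed log2 fold of the 531 genes was 0.65 pooled, 0.32 without these 2 libraries and 0.25 without either set, but the genes were chosen in a fit that holds the same other libraries, which favours their direction. An effect of OPFR in females stays open, because 0 genes were called without either set, where 3 OPFR and 4 control females remained and simulated data recovered 65.7% of 67 genes changed 1.5-fold. Of 100 groupings of the females, the real one included, the real split gave the most genes, 52 against at most 27. That is the smallest share 100 groupings can give. The real split also sets both control females of the run on one side and both OPFR females that stand apart on the other. The libraries are therefore not interchangeable, and chance is not read as excluded.

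The third pattern is that FM550 and OPFR fold changes moved together in males, across genes. By rank FM550 and BFR did so as well. Over genes with an average log2 CPM of at least 3, Spearman's rho was 0.81 with OPFR and 0.88 with BFR, against 0.47 simulated for each. Only the OPFR pair is weighed here. Chance spread of the shared controls, with no run among them, is argued against as the whole cause: the observed covariance was 2.14 times the highest simulated one. That simulation leaves out the run, which holds 5 of the 6 shared control males, and with the term the covariance was 0.0942 against 0.0983 simulated, with no excess over the same genes. On covariance, a batch of libraries 1 to 7 cannot be told apart from an effect common to FM550 and OPFR, because the 2 sets of genes disagreed. With the term, the excess covariance was -8.91% of the excess without it over 17135 genes, and 93.4% over the 10496 genes with an average log2 CPM of at least 3. By rank neither set held an excess with the term. Spearman's rho was 0.54 against 0.7 simulated in the same fit over 17135 genes, and 0.49 against 0.72 over the 10496 genes.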

How the results depend on the processing

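The fits with a term for libraries 1 to 7, without those libraries, without OPFR females 4 and 5, without both sets, without OPFR libraries 31 to 35 and with log2 library size were chosen after the data were seen, as was the sex difference over 4 treatments. Of 20 counts under 12 other settings each, 150 of 240 values stayed within 1.5 times. Of 31 named results, 241 of 372 values kept direction and side of the threshold, 108 were no longer past it, 8 became so and 15 reversed. In 371 fits without 1 library, 76 values of named results were no longer past the threshold and 0 reversed. The causes were not tested except as given in the weighing of libraries 1 to 7 and OPFR females 4 and 5. Tests of gene lists (camera with a preset or estimated correlation, fry, and their voom, surrogate variable and left-out versions) were not run, since no ID had a name. No paired analysis was possible because the replicate numbers only follow the order of the records. Simulated data recovered 88.1% of 67 genes changed 1.5-fold at the group sizes of the BFR male comparison and 80.6% at those of OPFR females, and fewer of the smaller changes. RLE size factors moved no count by over 1.5 times.

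DESeq2 called 2, 808 and 34 genes for BFR, OPFR and FM550 against control females, 3 and 1 for the sex by BFR and sex by FM550 interactions, 203, 11 and 373 for FM550 against OPFR, FM550 against BFR and OPFR against BFR in females, and 1, 11 and 60 in males. With no filter, FM550 against BFR males gave 2. Fits of only the groups compared gave 52 for OPFR females, 950 and 1230 for OPFR and FM550 males, 0 and 0 for FM550 and BFR against OPFR in females, 2 and 67 for FM550 and OPFR against BFR in males, and 1817 and 735 for OPFR and FM550 over both sexes. With 2 surrogate variables, OPFR and FM550 females gave 246 and 10, OPFR males 3930, FM550 and BFR against OPFR females 0 and 6, FM550 against OPFR and BFR males 1 and 5, OPFR against BFR males 549 and FM550 over both sexes 2176. There ENSRNOG00000047673 and ENSRNOG00000008700 reversed to 1.34 and 1.86 for FM550 against OPFR females. Limma voom with sample weights gave 282 for OPFR females, 3933, 3559 and 3616 for BFR, OPFR and FM550 males, 206 and 353 for the sex by OPFR and FM550 interactions, 0, 1 and 1342 for FM550 against OPFR, FM550 against BFR and OPFR against BFR females, 2 and 204 for FM550 and OPFR against BFR males, 1923 for sex in controls, and 3409, 2186 and 2408 for BFR, OPFR and FM550 over both sexes. ENSRNOG00000005707 reversed to -0.40 in OPFR females.

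The term for libraries 1 to 7 gave 243 for OPFR females, 0, 0 and 0 for BFR, OPFR and FM550 males, 395 and 60 for OPFR against BFR in females and males, and 0, 90 and 0 over both sexes. The covariances of FM550 with OPFR and BFR were 0.0258 and 0.0465 in females and 0.0942 and 0.059 in males. Without these libraries OPFR females gave 71, males 0, 0 and 0, FM550 against OPFR females 72, OPFR against BFR males 6, and both sexes 0, 4 and 0. Without OPFR females 4 and 5, OPFR females gave 75, FM550 and BFR against OPFR females 0 and 0, and OPFR over both sexes 1333. ENSRNOG00000020817 reversed to -0.11 against control and -1.09 against BFR, ENSRNOG00000005707 to -1.01 and ENSRNOG00000058560 to -0.51. Without both sets, OPFR females gave 0, males 0, 0 and 0, FM550 and BFR against OPFR females 0 and 0, OPFR against BFR males 6, and both sexes 0, 0 and 0, and the same genes reversed to -0.30, -1.09, -1.38 and -0.52. Without OPFR libraries 31 to 35, BFR and OPFR females gave 2 and 50, OPFR males 609, FM550 and BFR against OPFR females 0 and 0, FM550 against OPFR and BFR males 2 and 3, and OPFR over both sexes 918. ENSRNOG00000020817 reversed to -0.11 and -1.09, ENSRNOG00000005707 to -1.01 and ENSRNOG00000058560 to -0.52. With log2 library size BFR and OPFR females gave 2 and 258, FM550 against OPFR females and males 51 and 1, and OPFR against BFR males 21. Covariances with OPFR and BFR over genes with a log2 CPM of at least 3 were -0.00959 (reversed from 0.0145) and 0.00563 in females and 0.0349 and 0.0267 in males. With split controls they were -0.0185 and -0.00559 (both reversed) and 0.0404 and 0.0189.

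Leaving out 1 library at a time, counts against control ranged over 0 to 2, 172 to 1041 and 0 to 9 for BFR, OPFR and FM550 females, 941 to 3042, 1414 to 3012 and 1301 to 3084 for males, and 1134 to 3137, 2230 to 3911 and 794 to 2255 over both sexes. The interactions ranged over 0 to 0, 0 to 0 and 0 to 1. Between exposures, FM550 against OPFR, FM550 against BFR and OPFR against BFR ranged over 0 to 316, 0 to 0 and 2 to 544 in females and 0 to 0, 0 to 1 and 0 to 7 in males. Sex differences ranged over 14 to 436 in controls and 21 to 24 over 4 treatments.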

Other observations

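Exposure comparisons over both sexes, the fits without numbers 31 to 35, the between-sex correlations and the counts of libraries above 10 CPM were chosen after the data were seen, and the regrouping of samples was written before.

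A set of genes was near 0 in most libraries and high in a few from several groups. ENSRNOG00000047673 had a median of 1.3 CPM and passed 10 CPM in 11 of 47 libraries. It reached 757 and 1645 CPM in OPFR females 4 and 5, 263 in Control female 4, 225 in BFR female 5, and 213 and 195 in BFR males 3 and 5. ENSRNOG00000008700 passed 10 CPM in the same 11 libraries, and the 7 libraries in which ENSRNOG00000050023 did so were all among them. These libraries included controls and both sexes. No source was tested, because no ID had a name and no marker list could be read.

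Averaged over both sexes, OPFR and BFR differed in 814 genes by edgeR, 662 higher and 152 lower in OPFR, with controls entering only through the estimate of spread. A fit of only these groups called 709 (580 higher, 129 lower). Without OPFR females 4 and 5 there were 402 (312 higher, 90 lower), and without the 4 OPFR libraries numbered 31 to 34 there were 293 (207 higher, 86 lower). Without numbers 31 to 35 there were 144 (108 higher, 36 lower). FM550 and BFR differed in 35 genes (27 higher, 8 lower) and FM550 and OPFR in 1 gene on all libraries, and in 19 and 0 in fits of only the groups compared, with 2059 and 2748 genes at an unadjusted p under 0.05. FM550 against BFR gave 57 (32 higher, 25 lower) without OPFR females 4 and 5, 55 (28 higher, 27 lower) without numbers 31 to 34 and 48 (24 higher, 24 lower) without numbers 31 to 35, and no other tool was run on these means. ENSRNOG00000047261 was lower in OPFR than BFR, at -1.11 ± 0.18 on the log2 scale (edgeR adjusted p = 1.82e-04), and the adjusted p of edgeR was 2.08e-05 in the fit of only these groups and 0.0302 without numbers 31 to 35. Sample numbers run in blocks by treatment, so order and exposure were not separable.

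Female and male fold changes against control share no control library. Across 10496 genes with a log2 CPM of at least 3, which are not independent replicates, Spearman's rho between the sexes was 0.71 for BFR, 0.62 for OPFR and 0.39 for FM550, and Pearson's r was 0.60, 0.23 and 0.41. With the term for libraries 1 to 7 rho was 0.46, 0.65 and 0.38 and r was 0.49, -0.15 and 0.84, so for OPFR the sign differed between the measures. Without these libraries rho was -0.02, 0.41 and -0.05 and r was 0.01, 0.33 and -0.26. There every male fold change is against the 1 remaining control male, whose own deviation enters all of them. The lower values therefore do not show that the sexes disagree. For OPFR rho was -0.01 when OPFR females 4 and 5 were also left out and 0.16 when numbers 31 to 34 were. The term estimates 1 shift for both sexes, so an error in it enters both sides.

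Samples of each remaining comparison were regrouped 100 times, in fits of only the groups compared. Over both sexes the real split gave the most genes of the 100 for each exposure. It gave 1613 for BFR (at most 27 in another split), 1817 for OPFR (at most 793) and 735 for FM550 (at most 56). All 7 libraries numbered 1 to 7 lie on the control side of the real split. The OPFR split with 793 genes set all 7 on the exposed side, and another with all 7 on the control side gave 0. Regrouping here cannot tell exposure from the run. The sex difference over 4 treatments gave 22 genes, reached by 2 of 100 with a highest other of 227, FM550 against BFR males gave 2 genes, reached by 4 of 100 with a highest other of 7, and OPFR against BFR males gave 67, reached by 2 of 100. With this many comparisons regrouped, a share this small can come by chance, so none of the 3 counts is read as excluding it. For OPFR against BFR males another split gave 802 genes, which points to a structure of the samples other than exposure. For sex in controls, the 13 genes of the real split were reached by 5 of 100, so the number of genes alone does not exclude chance. It is excluded for the 10 genes over 8-fold apart, whose 23 female and 24 male libraries did not overlap, exposed libraries included. The highest other split gave 1872 genes and set 6 of libraries 1 to 7 on one side, and sex with a term for these libraries gave 13 genes. Where the real split gave 0 genes, all 100 splits give as many by construction, so regrouping tests nothing there. The highest others were 18 and 11 for BFR and FM550 females, 7, 25 and 26 for the BFR, OPFR and FM550 interactions, 4, 3 and 20 for FM550 against OPFR, FM550 against BFR and OPFR against BFR females, and 3 for FM550 against OPFR males.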
